A study of Mus musculus with 4 samples.

How the data were processed

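Caecal tissue of female CBA/J mice was profiled on Affymetrix arrays, with 1 array for each of 4 conditions: uninfected, S. Typhimurium, P. yoelii and both. Per the labels' protocols, tissue was snap frozen 4 days after infection or mock infection, total RNA was extracted with Qiagen reagents, and biotin-labelled cRNA was made by the standard Affymetrix protocol. Whether an array held RNA of a single mouse or a pool is not given in the sources used here. The authors deposited array intensities on a linear scale, as whole numbers with 1 value per probe set. The software that made them and the scaling between arrays are not given in the sources used here; the array medians of 118 to 124 show that the arrays had a common scale. There were no detection calls, and the Affymetrix control probe sets needed for a planned comparison of 3' and 5' signals were not analysed here, so RNA quality was not checked in that way.

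Of 45037 probe sets, 34945 had 1 gene symbol, 932 several and 9160 none in the platform annotation. For 34741 of those with 1 symbol the Entrez identifier matched a RefSeq gene table, and 0 symbols changed. Probe sets with several symbols or none were left out of the gene analysis.

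Values below the 20th percentile of an array (48 to 50) were raised to it, and log2 values were taken. A gene was represented by its brightest probe set over the 4 arrays, and counted as measured when that value reached the median of all probe sets on at least 1 array, which gave 12719 of 18193 genes. Of these, 5356 had several measured probe sets. For genes past 2-fold with several probe sets, all of them had the same direction for 539 of 592 with S. Typhimurium, 29 of 32 with P. yoelii, 251 of 278 with both infections against uninfected, 73 of 76 for both against S. Typhimurium and 231 of 258 for both against P. yoelii. A fold in which an array lay at the floor is a lower bound and is given as "at least". The floor limits how large a decrease can be seen, and dim genes are limited by background more than bright ones.

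Comparisons were differences of log2 values between pairs of arrays, and the departure from additivity was the difference made by S. Typhimurium with P. yoelii minus that without it. With 1 array per condition no test was run, as an additive model would leave only this departure as its residual, so genes were counted by size, at 2-fold and 4-fold. The number of arrays limits the precision of every value. Gene lists, 43 in all, for inflammatory and metabolic programmes, for resident and infiltrating cell types and for technical checks, were described by counts of measured members and by the median log2 difference. Its percentile among 10000 random lists of equal size, matched on mean expression in 10 bins, is a description of these arrays. In each comparison 41 lists had 3 or more measured members, and lists of genes drawn singly would put about 2.1 outside the 2.5 to 97.5 percentiles. Members of a real list may vary together, so more lists can lie outside without an effect of infection. With S. Typhimurium against uninfected, 19 lists lay above and 8 below, and with P. yoelii 19 and 4.

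The correlation between the differences made by each infection, which share the uninfected array, was set beside 100 simulations of unchanged arrays. Noise there, and in the simulated data below, was drawn independently for each value from the differences between the P. yoelii and uninfected arrays. Procedures were tested on simulated data made for the comparison of S. Typhimurium with uninfected, in which 200 genes were changed and 12304 entered the step: 42.6% of genes changed 2-fold, and 100% of those changed 3-fold, 4-fold or 8-fold, passed the 2-fold threshold, as did 80 of 12111 unchanged genes, and 1 of 60 unchanged lists lay outside the percentiles.

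Groups, comparisons, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took, per comparison, the 10 largest increases and 10 largest decreases of at least 2-fold whose other measured probe sets had the same direction, without clone or model names, then up to 4 members per list past 2-fold, largest first, and any member of the neutrophil chemoattractant, proinflammatory, IL-17 and IL-22, interferon gamma and IL-10 lists. A departure was made from it: genes at the floor on an array of the comparison were left out of the 10 largest, because values at the floor have no order, and were named only as list members. Alternatives were quantile normalization, median centring, no filter on dim genes, a stricter filter at the 75th percentile, the mean of a gene's probe sets, a 3-fold threshold and a higher floor at the array median. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.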

Results

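Gene expression was measured in caecal tissue of female CBA/J mice, an inbred laboratory strain, after infection with a non-typhoidal Salmonella serotype, with a rodent malaria parasite, or with both. S. Typhimurium is a bacterium that inflames the mouse caecum under suitable conditions, and Plasmodium yoelii is a parasite of mouse red blood cells. The 4 conditions were mock infection, S. Typhimurium alone, P. yoelii alone and both together, and tissue was taken on day 4 after infection or mock infection. For mice with both, the order and interval of the infections, and from which of them the day was counted, are not stated here. Each condition was represented by 1 array, so there were no replicates: differences between arrays have no replicate check, no p-values were computed, and counts and folds describe these arrays. The 4 arrays had median intensities of 118 to 124 over 45037 probe sets, and 12719 genes were bright enough to be measured. Across these genes, the P. yoelii array was closest to the uninfected array (Pearson r = 0.987 across genes, which are not independent replicates) and the S. Typhimurium array was farthest from it (r = 0.873).

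What S. Typhimurium alone did to the caecum was addressed by setting its array against the uninfected array. Interferon-induced genes and chemokines were among the genes with the largest increases: Cxcl9, a chemokine for activated T cells, was 43.9-fold higher, Ido1, a tryptophan-degrading enzyme, 41.9-fold, Cxcl11 35.9-fold, and the interferon-inducible GTPases Gbp6 and Iigp1 33.9-fold and 32.3-fold. Plet1, an epithelial surface protein, was 84.1-fold higher, from an intensity of 87 to 7317, and Reg3g, an antimicrobial lectin of the gut epithelium, was 32.8-fold higher. With the mean of a gene's probe sets Plet1 stood at 17.8-fold and Cxcl11 at 9.25-fold. Genes of epithelial metabolism and transport showed the largest decreases: Cyp2c55, a cytochrome P450, was 302-fold lower, from 15423 to 51, just above the floor of 49 and 131-fold with the higher floor, the water channel Aqp8 was 35.5-fold lower, and the sulphotransferase Sult1a1 was 35.9-fold lower. In all, 631 genes were at least 2-fold higher and 911 at least 2-fold lower, 12.1% of those measured, and 200 and 214 passed 4-fold.

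Of the 6 measured neutrophil chemoattractants, 4 were at least 2-fold higher, 1 was lower and 1 lay under 2-fold. Cxcl1 was 14.9-fold higher, and Cxcl5, Cxcl2 and Cxcl3, which lay at the floor on the uninfected array, were at least 28.8-fold, 11.1-fold and 6.12-fold higher, and 11.6-fold, 4.47-fold and 2.46-fold with the higher floor. Pf4, a platelet chemokine, was the lower member, with a log2 difference of -1.12. The median log2 difference of this list was 3.05 (1.73 with the higher floor), above all 10000 random lists of matched expression. Transcripts abundant in neutrophils were also higher, with 7 of 14 list members past 2-fold and none lower: S100a8 was at least 79.3-fold higher and S100a9 at least 64.7-fold, and 31.8-fold and 26-fold with the higher floor. Among proinflammatory cytokines and enzymes, 8 of 12 were at least 2-fold higher, 6 of them with the higher floor, including Il1b (log2 difference 4.00), Il33 (3.46) and Tnf (2.81), and Il6 was at least 14.3-fold higher (5.74-fold with the higher floor). Il18, a cytokine made by resting epithelium, and Il15 were lower, by log2 differences of -2.28 and -2.24.

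Interferon gamma response genes were higher almost as a block, with 22 of 23 at least 2-fold higher and a median log2 difference of 3.64. Ifng itself was at least 13.8-fold higher, from an intensity of 12 to 678, and 5.54-fold with the higher floor. Among type I interferon response genes, 12 of 21 were at least 2-fold higher, led by Ifit2 (log2 difference 3.70) and Zbp1 (3.30), although most of these genes also answer to interferon gamma. The list of NK and cytotoxic cell genes had 4 of 8 members higher, with Gzma and Gzmb, the granzymes of killer lymphocytes, at log2 differences of 4.12 and 3.12, the latter 2.12 with the higher floor. Ncr1, another of the 4, stood at 1.49, but at 0.47, under 2-fold, with the higher floor. Macrophage and monocyte genes had 9 of 16 members higher, led by Fcgr1 (3.11, and 1.88 with the higher floor), with the monocyte receptor Ccr2 8.0-fold higher (4.79-fold with the higher floor). With the mean of probe sets they stood at 1.60 and 3.23-fold. T cell genes did not shift, with 0 of 10 past 2-fold and a median of 0.01. Regulatory genes of the IL-10 list were higher for 9 of 13 members (6 with the higher floor), among them Socs3 (3.88), Cd274 (3.57) and Il1rn (3.35, and 2.48 with the mean of probe sets). Il10 itself was too dim to be measured, with intensities of 72 uninfected, 74 with S. Typhimurium, 78 with P. yoelii and 87 with both. The measured part of the IL-17 and IL-22 list showed no shift, with Il17a at a log2 difference of -0.39 and 7 of 8 members under 2-fold, and Il22 and Il17f were not analysed here.

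Epithelial antimicrobial genes moved in both directions. Of 20 measured members, 9 were at least 2-fold higher and 3 lower: Reg3b was higher by a log2 difference of 4.09 and Lcn2, which sequesters bacterial siderophores, by 4.17, whereas Itln1, a lectin of secretory cells, was lower at -3.92. Matrix proteases and their inhibitors were higher for 8 of 14 members, including Mmp10 at 28.2-fold and Mmp3 at 25.1-fold, which were near the floor on the uninfected array and stood at 12.9-fold and 10.5-fold with the higher floor. Acute phase genes were higher for 6 of 9, with Lrg1 at a log2 difference of 2.85. Cell division genes were higher by a median log2 difference of 0.70 over 23 genes, 4 of them past 2-fold, led by Rrm2 (1.20) and Cdc20 (1.19).

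Epithelial function genes were lower across several lists. Xenobiotic metabolism had 14 of 16 members at least 2-fold lower and a median log2 difference of -2.69, below all random lists, with the carboxylesterase Ces2a 33.6-fold lower and Cyp2d26 32.5-fold lower. Fatty acid oxidation and ketogenesis had 8 of 14 lower (median -1.31), led by Acaa1b (-4.40, and -3.52 with the higher floor) and Ehhadh (-2.58). Absorptive colonocyte genes had 9 of 19 lower, including the chloride exchanger Slc26a3 (-2.05) and Slc20a1 (-2.83, and -1.75 with the mean of probe sets). Enteroendocrine genes had 8 of 15 lower, among them Gcg, the precursor of glucagon-like peptides, at -3.12, and goblet cell genes had 4 of 17 lower and 1 higher, with Clca1 at -3.19 and Ang4 at -2.44 but Muc4 at 1.38. With the mean of probe sets Clca1 stood at -2.37 and Muc4 at 0.77, under 2-fold. Smooth muscle genes, which can reflect how much muscle a tissue piece held, were lower on the same array. Of these, 11 of 15 passed 2-fold (9 with the mean of probe sets), the median was -1.38, and Synm stood at -2.29. Whether the piece held less muscle or the muscle expressed these genes less cannot be told from these arrays. Stem and crypt base genes lay under 2-fold for 11 of 11. The difference for Nos2 depended on the floor placed under dim values: it was 1.04 with the floor used and -0.01 with the higher floor.

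**Figure D1:**
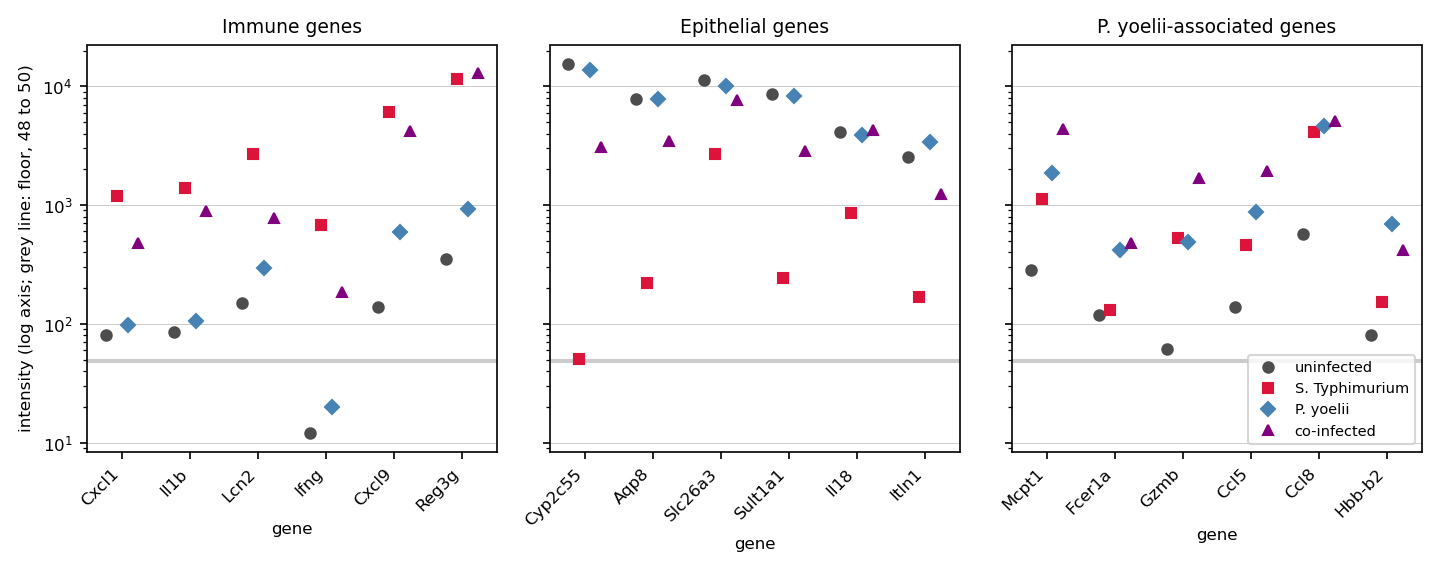
Intensity of 18 genes on the uninfected, S. Typhimurium, P. yoelii and co-infected arrays, 1 point per array, on a log axis, with a grey line at the floor of 48 to 50. Lcn2 stood at 2675 with S. Typhimurium alone and 773 with both infections, Aqp8 at 222 and 3461, and Mcpt1 at 1120 and 4357.

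The response to the malaria parasite alone was far smaller. On the P. yoelii array, 130 genes were at least 2-fold higher than on the uninfected array and 8 lower, 1.08% of those measured. The largest increases were in Defa31, an alpha-defensin of Paneth cells, at 33.3-fold, and in Apoa1, an apolipoprotein of small-intestinal and liver cells, at 9.96-fold. The beta-globin gene Hbb-b2 was 8.66-fold higher (5.7-fold with the higher floor and 3.36-fold with the mean of probe sets), the chemokines Ccl8 and Ccl5 8.11-fold and 6.35-fold, Gzmb 7.97-fold (3.97-fold with the higher floor), and the mast cell protease Mcpt1 6.53-fold. Defa31 and Apoa1 were read by probe sets of a class that can bind other transcripts. The largest decreases were in calcium and lipid genes: the epithelial calcium channel Trpv6 was 8.49-fold lower, the calcium-binding protein S100g 7.62-fold lower and the desaturase Scd1 4.79-fold lower.

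Interferon gamma response genes were higher with P. yoelii as well, for 13 of 23 members, with a median log2 difference of 1.49. With the mean of probe sets these were 11 of 23 and 0.97. Iigp1 was 8.93-fold higher, Gbp6 6.17-fold, and Cxcl9 stood at a log2 difference of 2.10 (1.14 with the mean of probe sets), while Ifng itself lay at the floor on both arrays, at 12 and 20. Mast cell genes were higher for 5 of 8 members (median 1.42), including Mcpt2 (2.47), the IgE receptor subunit Fcer1a (1.82) and Cpa3 (1.51). Ms4a2, another of the 5, stood at 1.33, but under 2-fold with the higher floor (0.31) and with the mean of probe sets (0.68). NK and cytotoxic genes were higher for 4 of 8, with Gzma at 2.59 and Nkg7 at 2.01 (1.12 with the higher floor), and monocyte and lymphocyte chemokines for 7 of 15. Macrophage and monocyte genes were higher for 5 of 16, led by Fcgr1 (1.59) and Ccr2 (1.42), which stood at 0.36 and 0.68, under 2-fold, with the higher floor and at 0.80 and 0.73 with the mean of probe sets. With either alternative 3 of 16 passed. In the T cell list 2 of 10 genes passed 2-fold, Cd3g and Cd3d at 1.12 and 1.05, with a list median of 0.03, and 1 of 10 with the higher floor.

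Of the neutrophil chemoattractants and proinflammatory cytokines, 0 of 6 and 0 of 12 measured members passed 2-fold with P. yoelii, and their medians were 0.06 and 0.01. Cxcl1 stood at 0.29, Il1b at 0.29 and Tnf at 0.27. Neutrophil genes had a median of 0.05 with 3 of 14 higher, among them S100a8 at least 3.86-fold and S100a9 at least 3.20-fold, but 0 of 14 with the higher floor. The antimicrobial list had 4 of 20 members at least 2-fold higher, including Reg3g at 1.39. Absorptive colonocyte genes lay under 2-fold for 19 of 19 and xenobiotic genes for 15 of 16, the exception being Cyp1a1, a target of the aryl hydrocarbon receptor, 3.26-fold lower. Smooth muscle genes lay under 2-fold for 15 of 15 (median -0.04). Hbb-b2 was the only member of 6 erythroid genes past 2-fold, and the median of that list was 0.14. Cd163, a macrophage haemoglobin scavenger receptor, was at least 4.25-fold lower, and 1.66-fold with the higher floor. These 2 arrays were the most alike of the 6 pairs: the central 95% of gene differences, uninfected minus P. yoelii, ran from -0.568 to 0.325 on the log2 scale.

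Genes that were higher with either infection overlapped. Of the 631 genes higher with S. Typhimurium and the 130 higher with P. yoelii, 82 were shared, against 6.45 for independent lists. Gzmb, Ccl8 and the interferon-inducible GTPases Iigp1 and Gbp6 were among the shared genes. Both comparisons used the same uninfected array, and part of the excess may come from it. Across genes the differences correlated at r = 0.305, where simulated unchanged arrays that share a control gave 0.499. The covariance was 0.0624 against 0.0334 in the simulation, a difference of 0.029. The simulated noise came from the P. yoelii and uninfected arrays themselves, so a real response to P. yoelii was counted as noise. These values therefore cannot separate a shared response from the effect of the shared array.

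Against the uninfected array, the co-infected array had 850 genes at least 2-fold apart, 449 of them higher and the rest lower. Plet1 was 75.6-fold higher, Defa31 40.9-fold, Reg3g 36.5-fold, Ido1 32.2-fold, Cxcl9 30.5-fold and Gzmb 27.5-fold (13.7-fold with the higher floor). With the mean of probe sets Plet1 stood at 16.6-fold and Cxcl9 at 17.3-fold. Sult1c2, a sulphotransferase, was 18.7-fold lower, Cyp4b1 17.3-fold lower and the magnesium channel Trpm6 16.1-fold lower (5.35-fold with the mean of probe sets). Interferon gamma response genes were higher for 22 of 23 (median 3.14), neutrophil chemoattractants for 4 of 6 (median 2.15) and proinflammatory genes for 7 of 12 (median 1.38). With the higher floor the latter 2 were 3 of 6 (median 1.06) and 4 of 12 (median 0.57). The mast cell list had its highest median here, with 6 of 8 at least 2-fold higher and a median log2 difference of 2.02, led by Mcpt2 (4.17) and Mcpt1 (3.94). NK and cytotoxic genes were higher for 6 of 8 (median 1.83). Among them, with the higher floor, Gzmk stood at 2.27-fold and Ncr1 at 1.07-fold, under 2-fold. Xenobiotic genes were lower for 10 of 16 (median -1.34), fatty acid oxidation genes for 4 of 14 (median -0.67) and absorptive colonocyte genes for 2 of 19 (median -0.44). Smooth muscle genes were lower for 10 of 15 (median -1.12), and for 6 of 15 with the mean of probe sets.

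**Figure D2:**
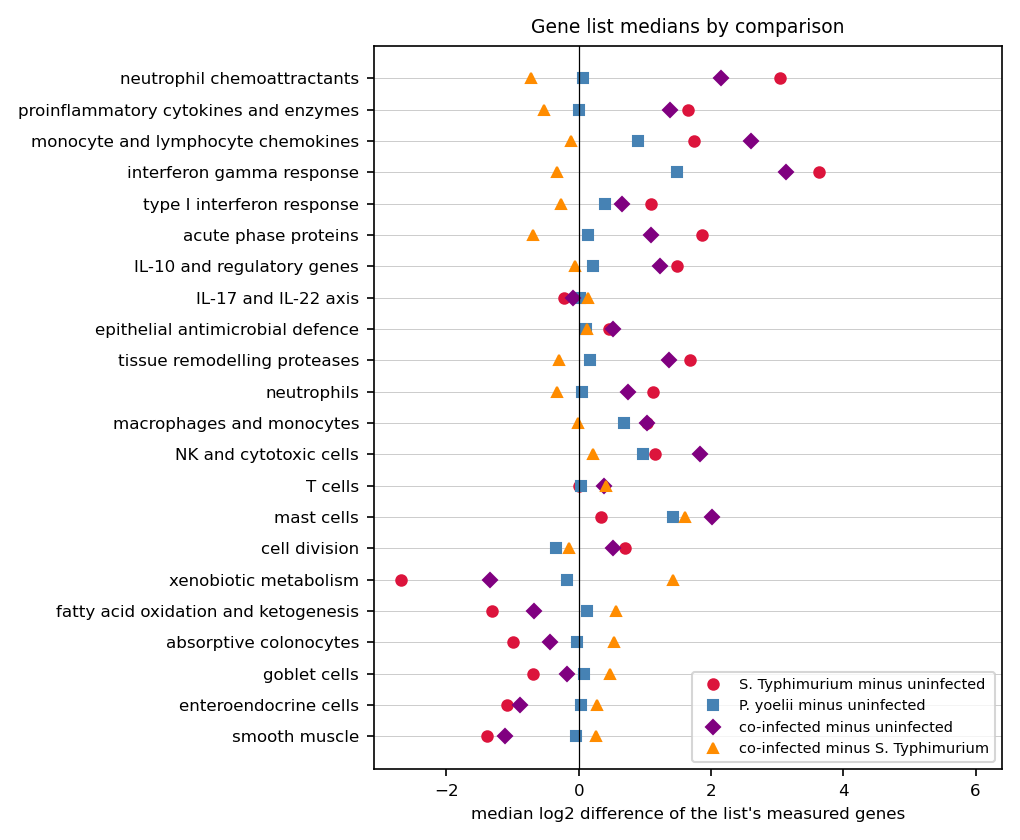
Median log2 difference of the measured genes of 22 fixed lists in 4 comparisons between single arrays, 1 marker per comparison. The median for neutrophil chemoattractants was 3.05 with S. Typhimurium alone and 2.15 with both infections, that for xenobiotic metabolism -2.69 and -1.34, and that for mast cells 0.34 and 2.02.

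The comparison of the co-infected array with the S. Typhimurium array asks what the parasite added to bacterial infection. Epithelial genes that were low with S. Typhimurium alone were higher: Cyp2c55 by 60.5-fold, at 3085 against 51 and 26.2-fold with the higher floor, Aqp8 by 15.6-fold, the sugar phosphate transporter Slc37a2 by 15.5-fold and Sult1a1 by 11.7-fold. Defa31 was 30.7-fold higher, Dbp, a clock-controlled transcription factor, 11.8-fold (5.39-fold with the higher floor and 3.36-fold with the mean of probe sets, and its other probe set was too dim to be measured), and the lectin Itln1 7.35-fold. Lower genes included the inducible heat-shock genes Hspa1a and Hspa1b, by 7.96-fold and 4.78-fold, in a list of immediate early and heat shock genes whose median was -0.37, with 3 of 17 lower. With S. Typhimurium alone that median was 0.36, with 5 of 17 higher. The lower genes also included inflammatory genes: Cxcl5 by 3.67-fold, Ifng by 3.65-fold, Il33 by 3.63-fold and Lcn2 by 3.46-fold. In all, 226 genes were at least 2-fold higher and 55 lower, and 3 of the lower genes passed 4-fold, Hspa1a, Hspa1b and Cd163, which was at least 5.18-fold lower, and 2.08-fold with the higher floor.

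Several inflammatory lists lay lower as lists, mostly by less than 2-fold per gene. The inflammasome and pyroptosis list lay higher, at a median of 0.25. Monocyte and lymphocyte chemokines had a median of -0.12, and 0.06 with the higher floor. Neutrophil chemoattractants had a median log2 difference of -0.72, with 2 of 6 at least 2-fold lower and Pf4 higher at 1.31. Cxcl1 stood at -1.32, Cxcl3 at -0.88 and Cxcl2 at -0.57. Proinflammatory genes had a median of -0.53, with Il6 at -1.54, Tnf at -0.65 and Il1b at -0.63, but Il18 was higher at 2.31, at 4254 against 858. The interferon gamma list had a median of -0.33, and 21 of 23 members lay under 2-fold, with Ifng and Socs1 (-1.38) past it. Acute phase genes had a median of -0.69, with Orm2 at -1.65 and Lrg1 at -1.12, while Saa2 and Saa1 were higher at 1.16 and 1.05. Tissue remodelling genes had 3 of 14 lower, Mmp10 (-1.55), Timp1 (-1.35) and Mmp3 (-1.34). The IL-10 list did not shift (median -0.05), with Il1rn lower at -1.14. Medians of the neutrophil chemoattractant, proinflammatory, interferon gamma and acute phase lists lay below all 10000 random lists. So did those of the type I interferon (-0.26), tissue remodelling (-0.30), unfolded protein response (-0.26) and immediate early and heat shock (-0.37) lists. The last of these is a technical check, so this rank was not specific to inflammatory lists. Of the 41 lists in this comparison, 10 lay above and 13 below the percentiles set for the random lists.

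Some inflammatory and antimicrobial genes were as high with both infections as with S. Typhimurium alone. Reg3g stood at 12918 against 11614, Reg3b at 16961 against 15509 and the phospholipase Pla2g2a at 4155 against 3811. Reg3b lay near the highest intensity of these arrays, 17893 and 18315, where a difference may not be readable. Mast cell genes were higher with both infections: 6 of 8 passed 2-fold (median 1.61), including Fcer1a (1.87) and Cpa3 (1.68). Lymphocyte lists had few members past 2-fold. Of the T cell genes these were 2 of 10, Cd3d and Cd3g at 1.17 each, with a list median of 0.42. Of the NK and cytotoxic genes they were 2 of 8, Gzmb at 1.67 and Gzmk at least 5.65-fold higher (2.35-fold with the higher floor). B cell genes had 0 of 12 past 2-fold (median -0.24, and 0.02 with the higher floor). The chemokine Ccl5 stood at 2.07. The macrophage and monocyte list did not shift (median -0.01).

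Xenobiotic genes were at least 2-fold higher for 11 of 16 members (median 1.42), fatty acid oxidation genes for 6 of 14 (median 0.57), absorptive colonocyte genes for 4 of 19 (median 0.53) and goblet cell genes for 2 of 17 (median 0.47). Among them were Cyp2d26 (2.54), Acaa1b (2.02, and 1.14 with the higher floor), Aqp8 (3.96) and Ang4 (2.32). Clca1, the other of the 2 goblet cell genes, stood at 1.58, and at 0.96 with the mean of probe sets, under 2-fold. Smooth muscle genes differed less, with a median of 0.26 and 0 of 15 past 2-fold.

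The difference made by S. Typhimurium in mice that carried P. yoelii was read from the co-infected and P. yoelii arrays. Plet1 was 39.4-fold higher (12.3-fold with the mean of probe sets), S100a8 14.5-fold, Reg3g 13.9-fold and S100a9 13.3-fold. Cyp4b1 was 17.5-fold lower, the sulphotransferases Gal3st2c 14.3-fold lower and Sult1c2 12.4-fold lower. In total 316 genes were at least 2-fold higher and 421 lower, against 631 and 911 without the parasite. Neutrophil chemoattractants were higher for 4 of 6 (median 2.02), with the higher floor for 3 of 6 (median 1.02), and interferon gamma response genes for 20 of 23 (median 1.65). Smooth muscle genes were lower for 9 of 15 (median -1.09), and for 6 of 15 with the mean of probe sets.

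For the parasite difference without and with S. Typhimurium, from arrays not shared, r was 0.105 across genes, and 32 of the 130 genes higher with P. yoelii alone were higher in both, against 2.31 for independent lists. The co-infected and P. yoelii arrays are not part of the comparison of S. Typhimurium with uninfected tissue, so both estimates of the bacterial difference can be set against each other. They had the same direction for nearly all genes past 2-fold in both: 273 were higher in both, against 15.7 for independent lists, 379 were lower in both, against 30.2, and 1 had opposite directions, S100g. Across genes r was 0.875 and the slope of the difference with P. yoelii on that without it was 0.586. Of the 200 genes at least 4-fold higher with S. Typhimurium alone, 175 had a smaller difference from uninfected tissue with both infections, and the median went from 2.85 to 2.31. Of the 214 genes at least 4-fold lower, 213 had a smaller difference, the median went from -2.61 to -1.54, and for 134 the gap between the arrays was at least 2-fold. Genes chosen for a large difference on an array tend to show a smaller difference on another by chance alone, and the arrays cannot separate that part.

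**Figure D3:**
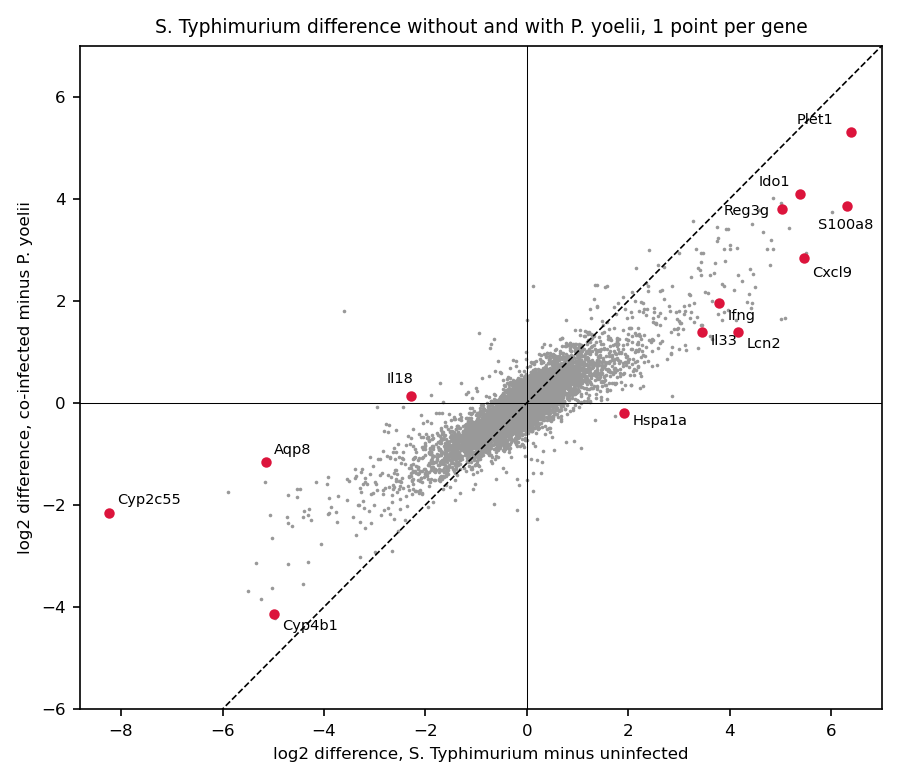
Log2 difference between the S. Typhimurium and uninfected arrays (horizontal) against that between the co-infected and P. yoelii arrays (vertical) for 12719 genes, 1 point per gene, with named genes in red and a dashed line where both differences are equal. Most genes with large differences lie between that line and the horizontal axis, as in Cyp2c55 at -8.24 and -2.15, Aqp8 at -5.15 and -1.16 and Lcn2 at 4.17 and 1.39.

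Departure from additivity was the difference between these estimates. It was at least 2-fold for 203 genes upward and 226 downward. Upward genes included Cyp2c55 (6.09, and 4.88 with the higher floor), Slc37a2 (4.14), Aqp8 (3.99) and Sult1a1 (3.61), whose decrease was smaller with both infections, and S100g (5.41), which was low with either infection alone. Downward genes included the GTPases Gbp6 (-3.43) and Iigp1 (-3.37), the chemokines Ccl8 (-2.71) and Cxcl9 (-2.62, and -1.92 with the mean of probe sets), and Gzma (-2.51), each higher with either infection alone and not higher in proportion with both. Ccl8, for instance, stood at 569 uninfected, 4107 with S. Typhimurium, 4617 with P. yoelii and 5098 with both. For Gbp6, Iigp1, Ccl8 and Cxcl9 a value in proportion would lie above the highest intensity on any array, 19998. Some downward departure was therefore built in for these genes, but not its whole size. With both infections they stood at 2760, 8525, 5098 and 4234, well below that limit. Gbp6, Iigp1 and Cxcl9 were lower there, by less than 2-fold, than with S. Typhimurium alone, at 4810, 9843 and 6108. Lcn2 (-2.77) and Timp1 (-2.40, and -1.52 with the higher floor) were also lower with both infections than with S. Typhimurium alone. The interferon gamma list had a median of -1.78 and 18 of 23 members past 2-fold downward. Gbp6, Iigp1 and Cxcl9, to which the limit on high intensities applies, are among its members. Of the xenobiotic genes, 13 of 16 passed 2-fold upward, with a median of 1.64.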

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

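Some genes responded in opposite directions to the same infection depending on the other, in values from single arrays whose difference was not tested. S100g, an intestinal calcium-binding protein, differed with S. Typhimurium by a log2 value of -3.61 without P. yoelii and 1.79 with it, and with P. yoelii by -2.93 without S. Typhimurium and 2.48 with it. Its intensities were 4654 uninfected, 380 with S. Typhimurium, 611 with P. yoelii and 2120 with both. Timp1, an inhibitor of matrix proteases, differed with P. yoelii by 1.05 without S. Typhimurium and -1.35 with it, but its value without S. Typhimurium was 0.17 with the higher floor. Pla2g3, a secreted phospholipase, differed with P. yoelii by -1.07 without S. Typhimurium and 1.24 with it.

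Probe sets without a single gene symbol, which the gene comparisons do not use, also differed from the uninfected array. At least 2-fold higher were 131 of them with S. Typhimurium, 38 with P. yoelii and 106 with both infections, and at least 2-fold lower were 166, 2 and 74.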

How the results depend on the processing

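All alternatives were planned. Quantile normalization and median centring left counts and slopes within 1.5 times of those given and reversed none of the gene differences or list medians called here. Over all alternatives, 83 of 96 counts, slopes and correlations, 5689 of 5963 gene differences and 1403 of 1446 list medians stayed within that limit. Beyond it moved 273 gene differences and 38 list medians, without a counted turn. For slopes and correlations the limit was a fixed difference instead. The filters on dim genes cannot change a gene difference, and median centring only adds a small constant. With the higher floor 175 gene differences moved, 1 turned and 847 stayed. With the mean of probe sets 98 moved and 925 stayed. The slope of the S. Typhimurium effect with P. yoelii on that without ran from 0.580 to 0.593. With the 3-fold threshold, which by construction admits fewer genes, counts higher and lower were 301 and 376 for S. Typhimurium against uninfected, 55 and 5 for P. yoelii, 233 and 118 for both infections, 87 and 13 for both against S. Typhimurium, 129 and 106 for both against P. yoelii, and 80 and 69 for the departure from additivity. The stricter filter left 5 of the 8 genes lower with P. yoelii. Turns were counted only for genes at least 2-fold apart and for lists outside the percentiles of the random lists. Other list medians also changed sign without being counted. B cell genes for both infections against P. yoelii, for instance, went from -0.05 to 0.01 with the higher floor. Counted directions turned in 6 cases, and the cause was not tested. Acute phase proteins with P. yoelii went from 0.14 to -0.03 without a filter on dim genes. Under the stricter filter, alternatively activated macrophage genes with S. Typhimurium went from 0.33 to -0.31, and endothelial and adhesion genes for both infections against P. yoelii from -0.25 to 0.60. With the higher floor, monocyte and lymphocyte chemokines for both infections against S. Typhimurium went from -0.12 to 0.06, B cell genes in that comparison from -0.24 to 0.02, and Nos2 with S. Typhimurium from 1.04 to -0.01. Signal near background limits such dim genes. No paired analysis was possible because each condition had 1 array.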

Other observations

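Other gene groups also differed between the arrays. Cell division genes were lower with P. yoelii alone, by a median log2 difference of -0.34 over 23 genes with 0 past 2-fold, where the median with S. Typhimurium was 0.70. Cholesterol synthesis genes were lower with P. yoelii by a median of -0.23 over 14 genes, again with 0 past 2-fold. Genes of the unfolded protein response were higher with S. Typhimurium for 4 of 15 members, led by Creld2 (2.14) and Asns (1.63), and had a median of 0.48. Adhesion molecules of inflamed endothelium were higher on that array, with Icam1 at 2.99 and Selp at 2.85 (1.77 with the higher floor and 1.32 with the mean of probe sets), while 10 of 13 members of the endothelial list lay under 2-fold. Among tight junction genes Cldn8 stood at -3.90 (-2.80 with the higher floor) and Ocln at -1.22 with S. Typhimurium but Cldn2, a pore-forming claudin, at 1.23, which was 0.58 with the mean of probe sets. Trpv6 was low on every infected array, at 95, 87 and 82 against 739 uninfected.

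Bounds for the tests below were set after the leading genes and list medians had been seen, and that on ileal genes of low caecal intensity was chosen only after the result was seen. That the ileal medians, the splits, the scalings, the clock phases and the dim Dbp probe set decide nothing was also judged after their values were seen. Genes named there were picked after their values were seen.

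The bacterial difference was smaller with P. yoelii in both directions, with a slope of 0.586. Noise in the difference without P. yoelii also lowers a slope, and the ratio of the spreads was 0.669. The slope takes the P. yoelii array as baseline, on which some of these genes were already higher. Genes at least 4-fold higher with S. Typhimurium alone had a co-infected median of 2.31 against uninfected and 1.66 against P. yoelii. For genes at least 4-fold lower these were -1.54 and -1.50. Scaling between the arrays as a cause of the low slope cannot be told from these tests. The higher of the slopes under quantile normalization and median centring was 0.586, but centring cannot change a slope, and quantile normalization moved 1 and 2 of 12719 gene differences beyond 1.5 times. A co-infected sample made partly of uninflamed tissue stays open. On the linear scale such a mixture would give the same inflamed share from every gene. Among genes whose difference with P. yoelii alone lay under 0.5 on the log2 scale, 91 genes at least 4-fold higher with S. Typhimurium gave 0.51 (interquartile range 0.34 to 0.66) and 191 genes at least 4-fold lower gave 0.73 (0.62 to 0.85), a difference of 0.22 with overlapping ranges. A weaker response of the mouse to S. Typhimurium during malaria is a candidate explanation that the design names, and a lower bacterial load or ordinary variation between mice could give the same arrays and was not tested.

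Several genes typical of the small intestine were higher on both arrays with P. yoelii, although 3 of 18 ileal enterocyte genes passed 2-fold with P. yoelii alone and 7 of 18 (median 0.79) for both infections against S. Typhimurium. Among these 7, Alpi, Cubn, Fabp2, Slc51a and Apob were lower with S. Typhimurium alone, by log2 differences from -3.29 to -1.14. Their values cannot be told apart from the smaller epithelial decrease with both infections. Other genes active in Paneth cells differed less than Defa31: Lyz1 stood at 0.41 and 0.07 and Mmp7 at 1.44 (0.81 with the higher floor) and 0.59. Lyz1, read by the same class of probe set as Defa31, stood at 4925 on the uninfected array, where a small share would be hidden. Mmp7 was also higher with S. Typhimurium alone, at 1.82 (1.19 with the higher floor). Defa3 was too dim to be measured, at 38 uninfected, 42 with S. Typhimurium, 34 with P. yoelii and 41 with both. These genes therefore do not decide. When the 4 arrays were split by parasite, 20 genes lay at least 2-fold apart between every array of either side, among them the defensins Defa31 and Defa39, Fabp6 (a bile acid binding protein of the ileum), Apoa1, Ccl25 (log2 difference 1.42 with P. yoelii alone), Slc6a19 (1.61), Spink1 (1.83) and Enpep, and also Dbp, Fcer1a, Cpa3 and Hbb-b2. The split that follows no infection gave 1 gene, but 3 splits are too few to exclude chance. Ileal tissue carried over into the samples may explain the pattern and cannot be told apart from a change in the caecum: the lower median of 18 ileal enterocyte genes over both comparisons was 0.34, a value that would have counted against it, but 11 of them lay above the 75th percentile of the uninfected array, such as Fabp2 at 14836, where a small share would be hidden. For the other 7 genes, which include Cubn, the lower median was 0.65, between the bounds set for and against carry-over. That median leaves out ileal genes too dim to be measured, and the filter keeps dim genes that rose on any array. With P. yoelii alone and for both infections against S. Typhimurium, Treh stood at 1.03 and 0.36 and Cyp3a11 at 0.65 and 0.03. Fabp1 stood at 0.25 and 0.33, Akp3 at 0.10 and -0.15 and Lct at -0.03 and 0.03. The value of 0.65 may therefore be too high, and it does not decide.

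Dbp, a transcription factor under clock control, stood at 83 uninfected, 54 with S. Typhimurium, 414 with P. yoelii and 636 with both. A different hour of harvest would move clock genes in opposite directions by phase. Day-phase minus night-phase medians were 0.26 with P. yoelii and -0.14 for both infections against S. Typhimurium. Both lay within the bound set against a different hour as the cause of the whole difference, but they do not decide. S. Typhimurium alone gave medians of -0.68 for night-phase and -0.15 for day-phase genes, so infection itself can move the second value. With P. yoelii alone the medians moved slightly by phase, 0.13 for day-phase and -0.13 for night-phase genes. Nr1d2, a day-phase gene, was higher in both comparisons, at 0.75 and 0.69. A faulty probe set may also be the cause: the smallest difference of the other probe set of Dbp was -0.06, but that probe set was too dim to decide. An effect of malaria on Dbp is left as an untested hypothesis.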
